A study of Agrobacterium sp. CGMCC 11546 with 6 samples.

How the data were processed

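Total RNA of a curdlan-producing Agrobacterium strain was sequenced after 24 h of curdlan fermentation in 3 wild type and 3 glnA deletion cultures, which the series' design text calls biological repeats. Libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Bowtie 0.12.2 and HTSeq are named in the submitters' processing notes. Their settings, the genome build, the annotation and the treatment of strand and of reads with several matches are not given in the sources used here. The deposited values are RPKM, 1 table per library, which the authors scaled to gene length and library depth, without pooling replicates. RPKM values are relative, so a library in which a few genes take fewer reads shows higher values for all other genes. Samples were put into groups by their titles, which also give the replicate numbers.

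Depth was recovered from the RPKM values themselves, since each equals a whole number of reads times a step set by gene length and depth. Relative depths came from the commonest ratio of low values between libraries, and the absolute depth was the candidate at which the recovered reads came closest to adding up to the depth. The chosen candidate was off by 0.252% and the next by 0.891%. Under that next candidate depths and reads per library would be 0.375 times as large, and the median length would be 2224 bp with 32.5% of lengths a multiple of 3. Whole reads, to within 0.001 read, were found for all 4540 features with reads, with a largest deviation of 8.19e-05 read. Under the chosen candidate the lengths had a median of 849 bp and 99.0% of them were multiples of 3, a property that the choice did not use, so they are called coding lengths. This property does not single out the chosen candidate. Candidates at 0.25, 0.5 and 1.25 times its depth gave 98.85%, 98.88% and 98.86%, but their recovered reads were off by 42.21%, 26.96% and 26.57%. For the 30 features with under 10 reads over all libraries the length is uncertain. On simulated tables all 6 depths and 99.05% of the features' reads were recovered exactly. The simulated reads added up to the depth by construction, apart from counting noise. They therefore could not test whether this holds for the real libraries. Depths ran from 5650536 to 8075395 reads. Counting intervals cover counting error only, since they leave out variation between cultures and between libraries. The reads also carry no molecular identifiers.

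The main test, most of the alternative settings, the gene lists and the rule for named genes were fixed before the data were examined. Values were taken as log2(RPKM + 1) without further scaling between libraries. Genes with a mean of at least 1 RPKM over the 6 libraries (4501, leaving out 39 lower features with reads) were tested with limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. Both strains shared 1 residual variance per gene. A fold change is on the log2(RPKM + 1) scale, which understates the change of low genes. A threshold of 2-fold was applied as a second count. Runs were counted as at least 4 consecutive identifier numbers called in the same direction and compared with 100 shuffles of the tested genes. The plan foresaw this only where a reference gave gene order, so identifier number was used in its place. The classes by level, the split by series of the identifier number, the comparison of wild type replicate 3 with the other libraries and the search for identifiers that lost nearly all reads were chosen after the data were seen.

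The test was checked on counts simulated from the real means and depths for the comparison of the strains, with an assumed dispersion of 0.01 (4503 genes tested). It recovered 64.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 5 false calls among 172. With 20 RPKM added in 1 wild type library (4504 genes tested), the shares were 38.8%, 61.2% and 78.8%, with 5 false calls among 124. The amount was the same for every gene, whereas the excess seen in wild type replicate 3 varied between genes. Few genes were changed, and no scale difference between the strains was simulated. The shares and false calls therefore need not hold for the real libraries.

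The files pair no identifier with a gene name, and no reference was used here. The 19 gene lists fixed beforehand (curdlan synthesis, nitrogen assimilation and others) therefore matched 0 members, and no list was tested. For this case the rule named the 2 identifiers with the largest rise and the 2 with the largest fall, among genes with an adjusted p under 0.05, at least 10 RPKM in the higher strain and no overlap between the strains. Other genes are described by group.

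Alternatives were other pseudocounts (0.1 and 10), other filters (none, or at least 10 RPKM), quantile normalization, TMM, median ratio and TPM scaling, limma without a trend, robust or with array weights, the replicate number as a block, each library left out in turn, and limma-voom on the recovered reads. TMM factors were computed with a written-out version of the method. They also scaled the library sizes of limma-voom, there computed on the recovered reads. After seeing the data, 3 more were added, namely subtraction of the excess of wild type replicate 3, omission of that replicate together with TMM scaling, and a filter at 100 RPKM. No pair of libraries within a strain agreed within sampling noise, the closest (wild type replicates 1 and 2) having a chi-square of 5.05 per degree of freedom.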

Results

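RNA sequencing compared an Agrobacterium strain that makes curdlan, a glucan secreted by the cell, with a mutant of the same strain that lacks glnA. The gene glnA encodes glutamine synthetase, which joins ammonia to glutamate and so supplies the cell with glutamine. Cells were taken after 24 h of curdlan fermentation. The wild type and the glnA deletion were each represented by 3 biological repeats, 1 library each. The values were RPKM (reads scaled to gene length and to library depth) for 5457 features, named only by identifiers that begin with Atu. The files did not pair these identifiers with gene names. The glnA transcript, the curdlan synthesis genes and the nitrogen regulatory genes were therefore not reported by name, and the loss of glnA in the libraries labelled as deletion was not checked by name.

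Reads were obtained for 4540 of the 5457 features, and the other 917 were listed at 0 in all 6 libraries. Whole reads could be recovered from the RPKM values. Wild type replicates 1, 2 and 3 held 7299497, 8075395 and 6451973 reads, and the deletion replicates held 5650536, 6710919 and 5887905 reads. At the median coding length of 849 bp, 1 read corresponded to between 0.146 and 0.208 RPKM. The 10 highest features took 25.2%, 24.4% and 19.3% of the reads in wild type replicates 1, 2 and 3, and 19.8%, 19.4% and 18.6% in the deletion replicates.

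Deletion of glnA was accompanied by a broad change of the transcriptome. Of 4501 genes with a mean of at least 1 RPKM, 1389 (30.9%) differed between the strains, 837 higher and 552 lower in the deletion libraries (limma with a mean-variance trend, Benjamini-Hochberg adjusted p under 0.05). Among them, 406 rose and 197 fell at least 2-fold. Changes of 4-fold or more were seen for 71 genes that rose and 61 that fell, and changes of 8-fold or more for 16 and 12. The median size of a called change was 0.91 on the log2 scale, and the median standard error of the called genes was 0.13. The values of the strains did not overlap for 1933 genes (42.9%), where chance gives 10% with 3 interchangeable libraries against 3. The libraries were not interchangeable, since the median RPKM of features with reads was 32.2, 32.1 and 54.5 in wild type replicates 1, 2 and 3. In the deletion replicates it was 43.3, 41.1 and 40.5, so shifts of whole libraries also move the share without overlap. Without wild type replicate 3, which stood apart from the other libraries, 2583 genes were called (784 rose and 188 fell at least 2-fold, or 456 and 382 after TMM scaling), and these 2583 held 1374 of the 1389, all in the same direction. The count was 922 with limma-voom on the recovered reads, which used TMM library sizes, and 774 of these were among the 1389. With array weights it was 2861.

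**Figure D1:**
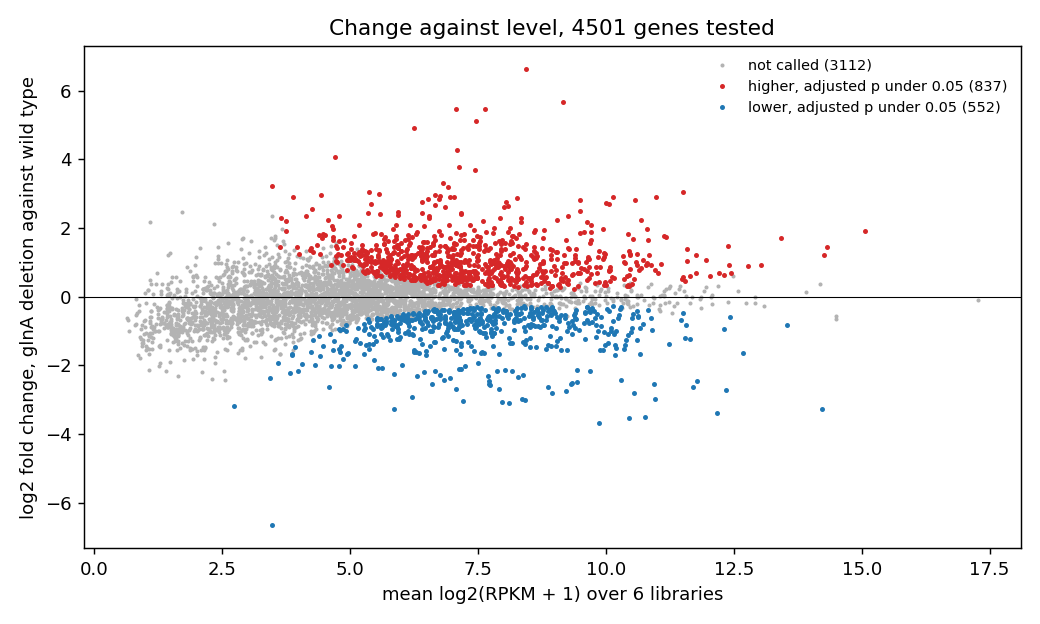
Log2 fold change of the glnA deletion against the wild type (y axis, on the log2(RPKM + 1) scale) against the mean log2(RPKM + 1) over 6 libraries (x axis), 1 point per gene tested. Red points (837) were higher and blue points (552) lower with an adjusted p under 0.05, and grey points (3112) did not pass.

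The largest rises past the test were those of a pair of genes with consecutive identifiers. Atu0485 (coding length 354 bp) rose from 34.1 ± 4.97 to 3480 ± 174 RPKM (SD, n = 3 per strain), a log2 fold change of 6.64 with a standard error of 0.11 (limma, adjusted p = 1.35e-11). Atu0486 (1092 bp) rose from 79.1 ± 11 to 4100 ± 269 RPKM (SD, n = 3 per strain), a log2 fold change of 5.68 with a standard error of 0.10 (limma, adjusted p = 3.32e-11). As ratios of mean RPKM these were 102-fold and 51.8-fold. Both stood at the end of a run of 7 consecutive identifiers that rose, with log2 fold changes between 0.49 and 6.64.

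The largest fall was that of Atu0602 (1440 bp), which had 1023, 1283 and 1179 reads in the wild type libraries and 0, 2 and 1 reads in the deletion libraries. Its level was 112 ± 14.8 RPKM in the wild type and 0.108 ± 0.104 RPKM in the deletion (SD, n = 3 per strain). Its log2 fold change was -6.66 with a standard error of 0.50 (limma, adjusted p = 1.13e-06), a value that depends on the pseudocount. The ratio of summed reads per depth was 971, with a 95% interval of 332 to 4710 from an exact Poisson comparison that covers counting error only. Atu0602 was the 1 identifier with at least 30 reads in each wild type library and at most 3 reads over the deletion libraries together, and 0 identifiers showed the opposite pattern. Whether Atu0602 is the deleted gene itself, rather than a gene with lowered expression, could not be checked, since no identifier is paired with a name. Atu1536 (732 bp) fell from 3390 ± 305 to 266 ± 65.9 RPKM (SD, n = 3 per strain), a log2 fold change of -3.69 with a standard error of 0.16 (limma, adjusted p = 1.73e-08).

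**Figure D2:**
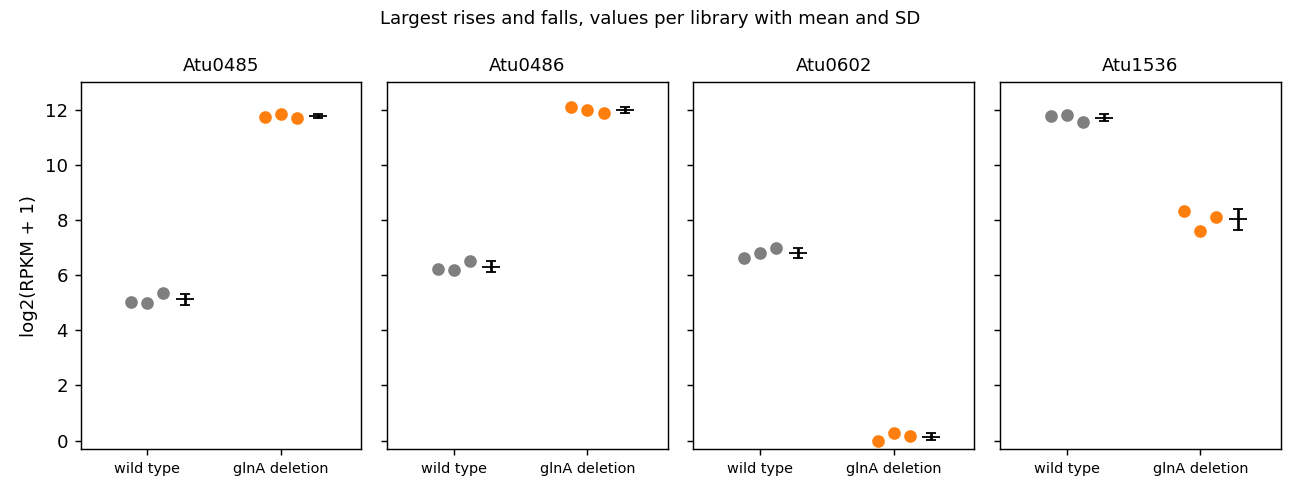
Values per library of the 2 genes with the largest rise (Atu0485, Atu0486) and the 2 with the largest fall (Atu0602, Atu1536) under the rule for named genes, y axis in log2(RPKM + 1). Grey points are wild type libraries, orange points deletion libraries, the bars give the mean and SD of 3 libraries on that scale, and the strains do not overlap for any of the 4 genes.

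Genes with consecutive identifier numbers changed together. Runs of at least 4 consecutive identifiers called in the same direction numbered 59, of which 37 rose and 22 fell, and they held 331 genes, 23.8% of the calls. In 100 shuffles of the tested genes the runs numbered 4.58 on average and at most 9. The share of genes called rose with level, from 0% at 1 to 10 RPKM to 70.6% at 300 to 1000 RPKM. The shuffles do not keep neighbours at similar levels together. If neighbours have similar levels, which was not tested, the shuffles give too few runs. The log2 fold changes of 4247 pairs of tested genes with consecutive numbers correlated at 0.48, against at most 0.04 in the shuffles (across genes, which are not independent). These fold changes include wild type replicate 3, whose low values were raised. Genes at 1 to 10 RPKM had a median log2 fold change of -0.40 with that library and 0.49 without it. Weakly expressed neighbours would share this shift, which the shuffles do not keep, so part of the correlation may come from it. Of the 331 genes, 324 kept their direction in all 22 alternative settings that tested them, and 223 were called under all 4 other scalings (TMM, median ratio, quantile and TPM). The runs numbered 160 without wild type replicate 3, 38 without deletion replicate 2, 38 with TMM scaling and 28 with limma-voom, which also used TMM. No reference was used here to place the identifiers in the genome, and the treatment of strand and of overlapping genes is not given in the sources used here, so reads shared between overlapping neighbours remain possible.

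The strongest rising run held 6 genes numbered in the 4000s. Their log2 fold changes lay between 2.77 and 5.47 with a median of 3.54, and their mean level went from 44.0 RPKM in the wild type to 650.2 RPKM in the deletion. A run of 12 genes in the 2000s rose by a median of 2.53 on the log2 scale, and by at most 3.23. The longest run held 17 genes in the 3000s and rose by a median of 2.21, with a range of 0.31 to 3.06, with 16 of its genes keeping their direction in all 22 alternatives and 12 called under all 4 other scalings. Another run of 15 genes in the 2000s rose by a median of 1.87, from a mean of 359.9 to 1670 RPKM, with 11 of its genes called under all 4 other scalings. All genes of these 4 runs were also called without wild type replicate 3.

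The falling runs held at most 9 genes. The strongest held 5 genes in the 1000s, Atu1536 among them, with a median log2 fold change of -3.50 and a mean level that went from 2834 to 248.3 RPKM. A further run of 5 genes in the 1000s had a median of -2.54. Runs of 5 genes had medians of -2.69 and -2.48 among identifiers under 1000, and another of 5 genes had a median of -2.63 in the 4000s. Every gene of these 5 runs was also called without wild type replicate 3 and kept its direction in all 22 alternatives.

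**Figure D3:**
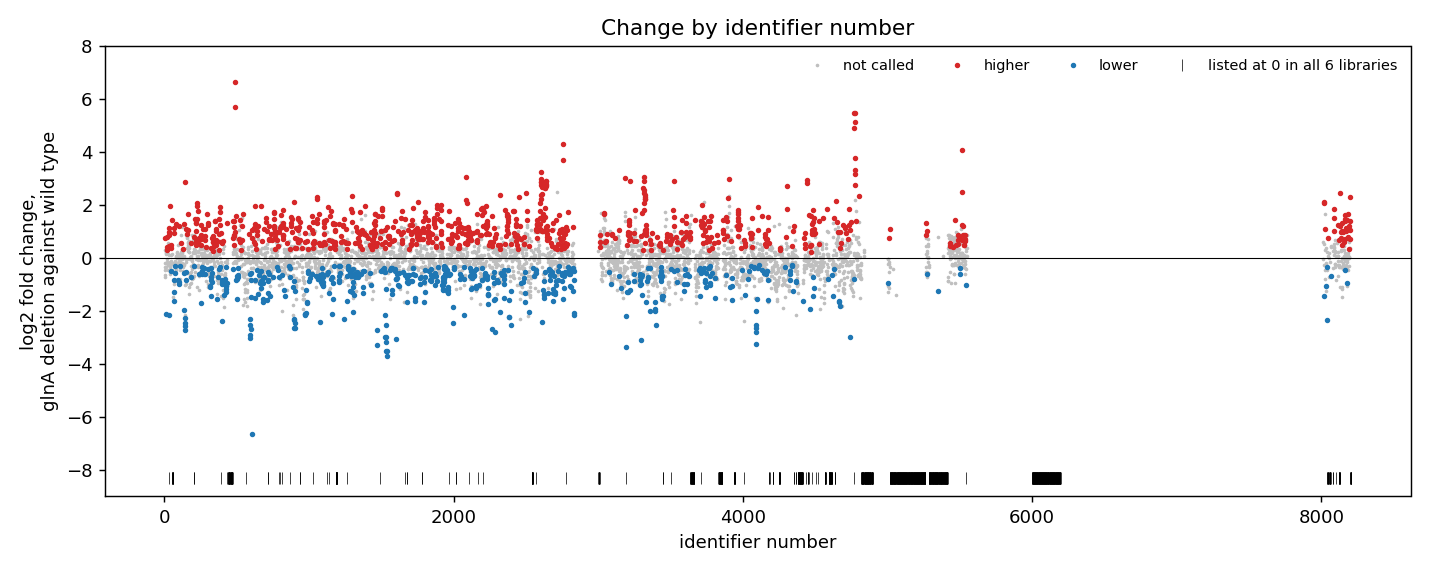
Log2 fold change of the glnA deletion against the wild type (y axis) by identifier number (x axis), 1 point per gene tested, with called genes in red (higher) and blue (lower) and the others in grey. Black ticks at the bottom mark the 917 identifiers listed at 0 in all 6 libraries, which include all 194 in the 6000s.

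Changes were called at all levels above 10 RPKM, in numbers that depended on the scaling and on wild type replicate 3. Among 236 genes with a mean of at least 1000 RPKM, 87 rose and 63 fell. Among 422 genes at 300 to 1000 RPKM, 160 rose and 138 fell, among 740 genes at 100 to 300 RPKM, 296 rose and 196 fell, and among 1241 genes at 30 to 100 RPKM, 269 rose and 135 fell. Of 1081 genes at 10 to 30 RPKM, 25 rose and 20 fell. Of 781 genes at 1 to 10 RPKM limma called 0, with 7 at an unadjusted p under 0.05, a median standard error of 0.92 and 4 calls by limma-voom. Without wild type replicate 3, 89 rose and 69 fell at 1000 RPKM and over, 165 rose and 145 fell at 300 to 1000 RPKM, 326 rose and 207 fell at 100 to 300 RPKM, 594 rose and 187 fell at 30 to 100 RPKM, 497 rose and 75 fell at 10 to 30 RPKM, and 217 rose and 12 fell at 1 to 10 RPKM. With TMM scaling 36 rose and 35 fell at 1000 RPKM and over, 71 rose and 54 fell at 300 to 1000 RPKM, 147 rose and 90 fell at 100 to 300 RPKM, 235 rose and 142 fell at 30 to 100 RPKM, 90 rose and a slightly larger number fell at 10 to 30 RPKM, and 7 rose and 8 fell at 1 to 10 RPKM.

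The share of higher against lower calls depended on the scaling between libraries. With RPKM as deposited 60.3% of the calls were higher. Under quantile normalization the share was 48.7% of 1736 calls, and without wild type replicate 3 it was 73.1% of 2583 calls as deposited and 46.4% of 2412 calls after TMM scaling. The median log2 fold change of the genes tested was -0.02 with all libraries and 0.32 without wild type replicate 3. The TMM scale of wild type replicate 3 was 1.492, against 0.792 for replicates 1 and 2. Its median ratio scale was 1.378, against 0.816 and 0.818. As deposited, its genes at 100 to 500 RPKM differed from theirs by a median ratio of only 1.04. Both scalings therefore lowered its well expressed genes against the other wild type libraries. The 4 named genes kept their direction and an adjusted p under 0.05 in every alternative that tested them.

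Wild type replicate 3 differed from every other library in its weakly expressed genes. Among the 1073 genes at 1 to 10 RPKM in wild type replicates 1 and 2, 97.95% were higher in replicate 3, with a median excess of 19.1 RPKM and an interquartile range of 11.3 to 28.2 RPKM. The same measure in the deletion libraries, each set against the mean of the other 2, lay between -0.229 and 0.233 RPKM. The median excess in replicate 3 was 17.1 RPKM for genes at 1 to 2 RPKM and 18.6 RPKM for genes at 20 to 50 RPKM, and genes at 100 to 500 RPKM differed by a median ratio of 1.04. Across 4501 genes on the log2(RPKM + 1) scale, wild type replicates 1 and 2 had a Pearson correlation of 0.994, and the deletion libraries correlated with each other at 0.988 to 0.991. Replicate 3 correlated at 0.927 with both other wild type libraries, below the 0.938 to 0.946 between those libraries and the deletion libraries. With the deletion libraries replicate 3 correlated lower still, at 0.867 to 0.873. These correlations are across genes, which are not independent replicates.

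**Figure D4:**
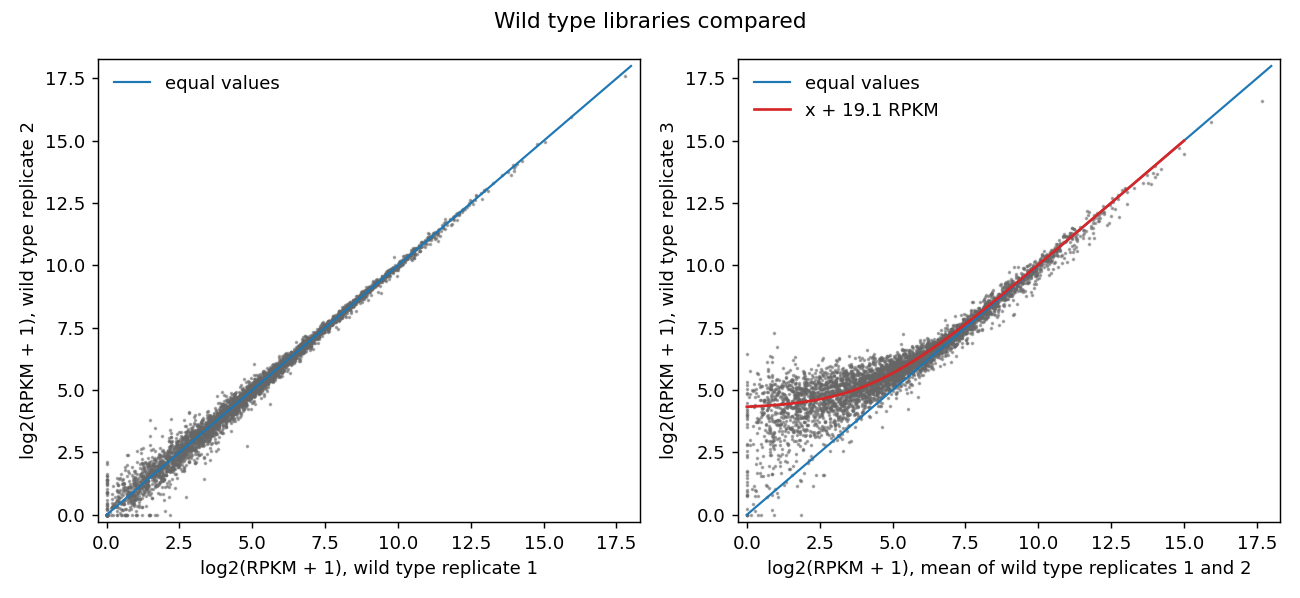
Wild type replicate 2 against replicate 1 (left) and replicate 3 against the mean of replicates 1 and 2 (right), both axes in log2(RPKM + 1), 1 point per feature with reads. Blue lines mark equal values, and the red line adds 19.1 RPKM to the x value, where the weakly expressed features of replicate 3 scatter.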

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

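The filter at 100 RPKM, the subtraction of the excess of wild type replicate 3 and its omission together with TMM scaling were chosen after seeing the data, and the other alternatives before. The 4 named genes kept their direction and an adjusted p under 0.05 in all 87 alternative results, with log2 fold changes from 6.31 to 6.90 for Atu0485, from 5.43 to 5.80 for Atu0486, from -9.68 to -3.58 for Atu0602 (the deletion libraries hold at most 2 of its reads each) and from -4.14 to -3.49 for Atu1536. The count of changed genes (1389) stayed within 1.5 times in 18 of 22 alternatives. It was 2861 with array weights, which gave wild type replicate 3 a weight of 0.050, 922 with limma-voom, and 2412 without wild type replicate 3 after TMM scaling, where 34 of the 1389 genes changed sign. In the other alternatives none of the 1389 that were tested changed sign. A similar count did not always mean the same genes: TMM scaling called 1016, of which 789 were among the 1389. Leaving out 1 library gave between 1125 and 2583 changed genes, between 525 and 972 changed at least 2-fold (603 with all libraries) and between 38 and 160 runs (59 with all libraries). The upper value came each time without wild type replicate 3, and the 38 runs without deletion replicate 2. Genes changed at least 2-fold numbered 1000 with array weights and 364 with the filter at 100 RPKM. The runs numbered 183 with array weights, 38 with TMM scaling, 28 with limma-voom, 25 with the filter at 100 RPKM and 132 without wild type replicate 3 after TMM scaling. The filter at 100 RPKM tested 1398 genes. TMM gave wild type replicate 3 a scale of 1.492, against 0.792 for replicates 1 and 2, and limma-voom also used TMM. With TMM scaling, 147 genes rose and 90 fell at 100 to 300 RPKM, against 296 and 196 as deposited. At 100 to 500 RPKM replicate 3 differed little as deposited, with a median ratio of 1.04. Whether this scale lowered the counts was not tested by itself. For the other settings the cause was not tested. The mean correlation of wild type replicate 3 with replicates 1 and 2 was 0.927, and 0.964 with a pseudocount of 10 and 0.985 with the filter at 100 RPKM, where low values count for less. The median log2 fold change of the genes tested was 0.32 with array weights, 0.28 after subtraction of 19.1 RPKM from wild type replicate 3 (1779 calls) and -0.11 with limma-voom. With the replicate block 1440 genes were called. Deviations from the strain means correlated at 0.038, -0.067 and -0.046 between libraries of the same number. Between libraries of different numbers they correlated at -0.051 to 0.078. These values gave no sign that the numbers pair the cultures. They cannot exclude it, because the raised low values of wild type replicate 3 dominate the wild type deviations. Set tests of the gene lists, and results for the curdlan genes and glnA, were not run, since no identifier is paired with a name. At these depths, genes near 1 RPKM rest on about 5 to 7 reads per library at the median length.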

Other observations

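The identifiers without reads were not spread evenly over the numbering. All 194 identifiers in the 6000s and 364 of 541 in the 5000s (67.3%) were at 0 in all 6 libraries, against 1.99% in the 2000s and 2.41% in the 1000s. In the 4000s the share was 19.4%, in the 8000s 18.2%, in the 3000s 7.37% and below 1000 5.12%. Of the 917 identifiers, 767 (83.6%) lay in 15 runs of at least 10, the longest with 202 identifiers. Among the tested genes 172 rose and 124 fell below 1000, 198 and 167 in the 1000s, 188 and 120 in the 2000s, 134 and 84 in the 3000s, 83 and 44 in the 4000s, 27 and 6 in the 5000s and 35 and 7 in the 8000s. In the same order 904, 925, 786, 885, 692, 176 and 133 genes were tested. Of these, 32.7%, 39.5%, 39.2%, 24.6%, 18.4%, 18.8% and 31.6% were called, against 30.9% of all tested genes. Without wild type replicate 3, 351 rose and 163 fell below 1000. The later series then gave 368 and 191, 357 and 142, 405 and 108, 259 and 73, 91 and 7, and 57 and 11. With TMM scaling more genes fell than rose below 1000, with 107 and 119, and the other counts were 118 and 99, 134 and 76, 113 and 71, 71 and 53, 18 and 6, and 25 and 6.

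All tests below on the 3 patterns were chosen, or their outcome was already visible, after the patterns had been seen. The tests on a mislabelled library and on the deletion libraries were also changed after a first result: they first gave 0.0161 with genes chosen from all 6 libraries, and 6.96 and 1.4 with genes grouped and measured on the same wild type libraries. The 6 choices of libraries and the separation of spread from shift were added last, and the criterion for the latter was changed after its values were seen. The count over splits was planned, but its outcome was seen before the criterion was written down.

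A hypothesis for the identifiers at 0 is that they form stretches of the annotation that this strain lacks or that take no reads. The longest run of 202 compares with at most 7 in 100 shuffles. Genes present but too little transcribed to be seen are argued against, provided that the added reads of wild type replicate 3 reach every gene: of 925 identifiers at 0 in the other 5 libraries, 99.1% were at 0 there too, against 14% of 43 identifiers with 1 to 5 reads in the other libraries. Those 43 had a median of 6 reads in wild type replicate 3, so the added reads were fewer there than in other weakly expressed genes. Absence from the genome, sequence divergence and discarded multiple matches stay open, since no genome was used here, and no biological explanation was tested.

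The raised low values of wild type replicate 3 may come from an equal amount of reads per kilobase added to every gene, as genomic DNA in the RNA would give. The median excess of genes at 20 to 50 RPKM was 1.09 times that of genes at 1 to 2 RPKM (95% bootstrap interval over genes 0.97 to 1.27), although their levels differ 21.98-fold. Single genes varied far more than an equal amount with counting noise alone would give, since the level in replicate 3 divided by the mean of replicates 1 and 2 plus 19.1 RPKM had, over the 1073 genes at 1 to 10 RPKM, an interquartile range of 0.708 of its median, against 0.12 in simulations, but differences between cultures also widen this spread, so the equal amount holds at most for medians. An equal amount that takes 8.16% of the library would leave an excess of 19.1 RPKM below 1 RPKM, where 14.1 was measured. It would leave 19 at 1 to 2, 18 at 10 to 20 and 16.5 at 20 to 50 RPKM, where 17.1, 21 and 18.6 were measured. An equal amount would thus give a smaller excess at 20 to 50 than at 1 to 2 RPKM, but the measured median was slightly larger. At 50 to 100, 100 to 500 and above 500 RPKM it would leave 13.4, 3.89 and -67.7, where 15.2, 8.04 and -39.7 were measured. The medians therefore follow an equal amount only roughly. A mislabelled deletion library is argued against, since over 370 genes with a mean of at least 100 RPKM that changed at least 2-fold between the other libraries, replicate 3 lay 0.0368 of the way from the other wild type libraries to the deletion; over all 972 such genes of any level it lay at 0.356, with 0.581 for the 784 that rose, which an added amount also raises, and -0.0311 for the 188 that fell. Calls among genes under 30 RPKM went from 45 to 801 without this library (at most 25 without any other). Over the 1757 genes tested in both fits, the smaller standard errors alone took the calls from 47 to 608, and the shifted fold changes alone to 98, so the shift of the wild type mean is argued against as the whole cause of the count. The direction moved with the shift, since 247 of the 608 calls were higher in the deletion and 714 of the 801. Uneven DNA coverage, or low-level transcription across the genome in that culture, stays open and was not tested.

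Without wild type replicate 3, weakly expressed genes stood higher in the deletion: with genes grouped by replicate 1 of each strain, the median ratio of deletion replicates 2 and 3 to wild type replicate 2 was 1.71 at 1 to 2 RPKM, 1.38 at 10 to 20 RPKM, 1.24 at 20 to 50 RPKM and 1.01 above 500 RPKM. An equal amount per kilobase added in the deletion libraries is argued against as the whole cause, since the excess at 20 to 50 RPKM was 8.15 to 11.5 times that at 1 to 2 RPKM over 6 choices of the libraries grouped by and measured. So is 1 scale factor, since the ratio at 1 to 2 RPKM was 1.21 to 1.38 times that at 20 to 50 RPKM over these choices, against at most 1.13 between libraries of the same strain. Both rest on 2 wild type cultures, 1 of them measured at a time. A mixture of these causes, and a response of weakly expressed genes to the loss of glnA, stay open and were not tested.

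The comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. The real split was the 1 split to reach its count each time, with 1389 changed genes, 603 genes changed at least 2-fold and 59 runs. In limma the other splits gave at most 0 of each, with at most 267 genes at an unadjusted p under 0.05. Each other split placed libraries of both strains in each group, so any strain difference widened its residual spread. Low counts there were therefore likely from the start, and no conclusion is drawn from the contrast with the real split.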
